A study of Homo sapiens with 24 samples.

How the data were processed

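Poly-A RNA was sequenced from CD14-positive human myeloid cells of 3 healthy donors, untreated or treated with TGF-beta 1 for 4, 8, 12 or 36 h, with TruSeq v2 libraries. The authors' table of raw read counts, as used here, holds 65216 Ensembl gene identifiers and 1 column for each of 22 libraries. The submitters' processing notes name genome build hg38, TopHat2 2.0.12, Bowtie2 2.2.3.0, SAMtools 0.1.18.0 and HTSeq 0.5.4p3. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands may not be separated. The labels describe 24 libraries. All 22 columns were used, and the 2 libraries without a column in this table, the TGF-beta library of donor 1 and the untreated library of donor 3 at 4 h, were not analysed here. Groups and donor numbers were taken from the labels.

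Identifiers were named with a gene name table (56321) and GENCODE release 29 (491 more), and 8404 had no name. Coordinates are those of GENCODE 29 on hg38. Y-linked genes, XIST and further excluded identifiers were left out of the tests. Total counts ran from 16.8 to 32.7 M per library (median 25 M), and TMM factors from 0.85 to 1.2. No replicate pair agreed within sampling noise: the chi-square per gene between replicates ran from 27.5 to 63.3. Where few reads carry a value, the text gives the number of reads.

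Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr on the 8 groups, which left 18719, and scaled with TMM. A robust quasi-likelihood model with 8 group means and no donor term (14 residual degrees of freedom) was fitted to all libraries. The comparisons were TGF-beta against untreated at each time, the average of these, untreated 36 h against 4 h, the TGF-beta effect at 36 h against that at 4 h, and any difference of the effect among the 4 times. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Because the labels number the donors, the same tests were also run with donor as an additive block (12 residual degrees of freedom). The blocked count is given beside the gene counts of comparisons that it moves by over 1.5 times. For members of gene lists it is given only in part, so a list without it need not be stable under the block. After the groups were accounted for, expression of libraries of the same donor correlated at 0.30 to 0.68 (median 0.50, 70 pairs), and that of different donors at -0.54 to 0.30 (median -0.27, 141 pairs). Deviations from the mean of a group sum to 0. Where libraries of a donor correlate, this pushes the values between donors below 0. 0 libraries were best correlated with a library of another donor.

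Gene lists, 43 lists of 996 genes in all, were fixed before the data were examined. Lists with at least 5 tested genes were tested with limma camera on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. The adjusted p with the correlation estimated for each list is given beside each call. Member counts use the test over all genes, and counts adjusted over the list alone are given in brackets.

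Genes to be named were chosen by a rule set beforehand. For each TGF-beta comparison these were the 10 largest rises and 10 largest falls among named genes that passed the test, had a mean of at least 2 log2 CPM and moved the same way in each donor with both libraries. At 4 h only donor 2 had both. For untreated 36 h against 4 h and for the difference of effects, 5 per direction were taken, without the donor rule for the latter. For each list described, up to 4 members past the test with the largest changes could be named, and otherwise the 2 with the highest expression. SMAD7, TGFBI, SKIL, PMEPA1 and TGFB1 were named as checks of the treatment. Some genes that the rule selects are not reported here. All named genes came from the fit without the donor term.

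The tests were checked on simulated data in which 200 of 18719 genes were changed. The remaining members of 1 list, the targets of hypoxia-inducible factor, were raised 1.5-fold. Each change was the same at all 4 times, so the recovery in the average holds for constant effects. Without the donor term, 11.9, 37.3 and 57.6% of genes changed 1.5, 2 and 4-fold were recovered at 4 h, 25.4, 46.3 and 66.7% at 12 h, and 61.2, 71.6 and 83.3% in the average. At most 0.0108% of unchanged genes were called without the donor term and 0.0541% with donor as a block, and 0 of the other lists. Apart from group and donor differences, counts were simulated independently for each gene. The list test was therefore not checked on correlated genes. The alternatives tried were DESeq2 1.42.0 with its own size factors, RLE scaling, no filter and a stricter filter (at least 1 CPM in 11 libraries), the donor block, each donor left out, only the libraries of the groups compared, counts summed per donor, limma fry, and, added after seeing the data, other choices of times and the donor block with an estimated correlation. Treatment labels were also exchanged between libraries to count genes in other splits.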

Results

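Gene expression was measured by poly-A RNA sequencing in CD14-positive human immature myeloid cells, taken from the blood mononuclear cells of 3 healthy donors and cultured with or without transforming growth factor beta 1 (TGF-beta). TGF-beta is a secreted cytokine that signals through SMAD transcription factors. RNA was taken after 4, 8, 12 and 36 h, which gave 8 groups of treatment and time. Read counts of 22 libraries were analysed. The groups at 8, 12 and 36 h held 3 libraries each, 1 per donor, and both groups at 4 h held 2, with only donor 2 in both. Libraries held between 16.8 and 32.7 M counted reads, with a median of 25 M. Values are read counts scaled to library size (CPM), given as mean ± SD over the libraries of a group, and log2 fold changes from edgeR, given with their SE. Over all libraries, the first principal component held 44.9% of the variance and the second 13.3%. The questions were which genes TGF-beta changed at each time, how the untreated cells changed in culture, and whether the effect of TGF-beta differed between times.

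Genes that TGF-beta is known to induce were examined first, as a check of the treatment. SMAD7, the inhibitory SMAD that limits the pathway (chromosome 18, 48919853 to 48952052 on hg38), stood at 359 ± 9.59 CPM with TGF-beta and 106 ± 5.78 CPM without at 4 h (n = 2 each). At 36 h it stood at 121 ± 8.32 and 39.1 ± 9.77 CPM (n = 3 each). It rose at every time, by log2 fold changes of 1.76 ± 0.22, 2.51 ± 0.19, 2.74 ± 0.19 and 1.63 ± 0.18 at 4, 8, 12 and 36 h. PMEPA1, a membrane protein that binds SMADs, rose by 2.43 ± 0.60, 4.14 ± 0.53, 5.14 ± 0.57 and 2.97 ± 0.52. TGFB1, the gene of the ligand itself, rose by 1.39 ± 0.19, 1.62 ± 0.16, 1.52 ± 0.16 and 0.54 ± 0.16. TGFBI rose by 1.48 ± 0.17, 1.45 ± 0.17 and 1.02 ± 0.17 at 8, 12 and 36 h. At 4 h its log2 fold change was 0.73 ± 0.21, with an edgeR adjusted p of 0.0595, and with donor as a block 0.87 ± 0.15, with an adjusted p of 0.000769. SKIL, which encodes the SMAD repressor SnoN, rose by 0.72 ± 0.18, 1.13 ± 0.18 and 1.03 ± 0.18 at 8, 12 and 36 h. At 4 h its value was 0.37 ± 0.22, with an edgeR adjusted p of 0.474.

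**Figure D1:**
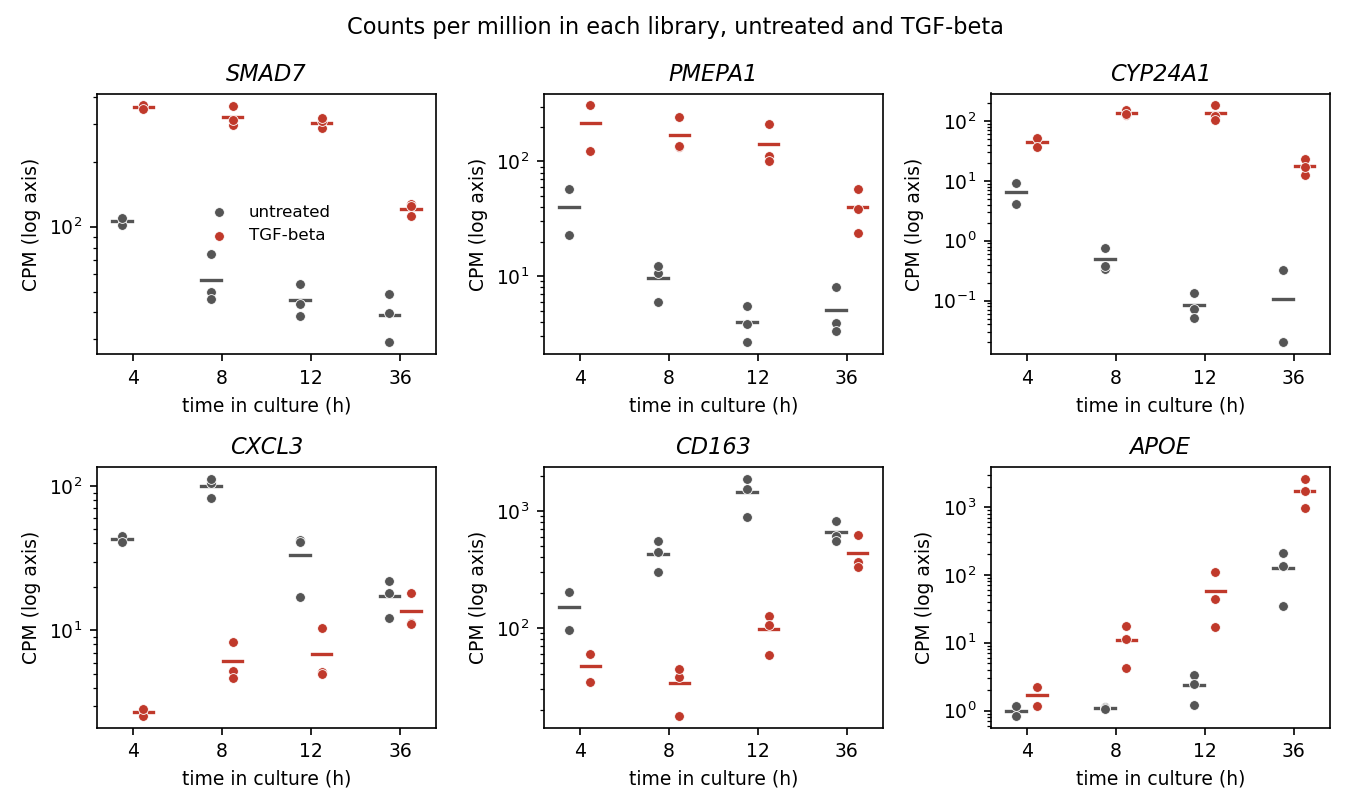
CPM on a log axis in each library for 6 genes, by hours in culture, with grey points for untreated and red points for TGF-beta libraries and a bar at the mean of each group (2 libraries per group at 4 h, 3 at the other times). Libraries with no CYP24A1 read are drawn at the foot of that panel. The SMAD7 points with TGF-beta lie above those without at each time, and the APOE mean goes from 0.991 to 127 CPM in untreated cells between 4 and 36 h.

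After 4 h, the protease genes MMP2 and PLAU and the transcriptional regulators ID2 and SOX4 had some of the largest rises among named genes. The chemokine genes CXCL3 and CXCL2 had some of the largest falls. As lists, matrix and protease genes (camera adjusted p 0.106) and inflammatory cytokines (0.994) were not called at 4 h. Untreated libraries were of donors 1 and 2 and treated ones of donors 2 and 3. Without a donor term, treatment and donor are therefore not fully separated. With donor as a block, LPAR5 and PLAU changed by 3.17 and 3.22, and RGL1 and PLA2G7 by -2.46 and -1.91. ID2, an inhibitor of basic helix-loop-helix factors, stood at 454 ± 0.822 CPM with TGF-beta against 59.6 ± 0.166 without (log2 fold change 2.93 ± 0.32). The transcription factor SOX4 rose by 2.82 ± 0.26 and the stress gene GADD45G by 2.81 ± 0.42. MMP2, a gelatinase, rose by 3.39 ± 0.79, and PLAU, which encodes urokinase, by 2.86 ± 0.67. LPAR5, a lysophosphatidic acid receptor, rose by 3.02 ± 0.52, LINC03040 by 2.75 ± 0.64 and PALD1 by 2.65 ± 0.46. CYP24A1, the enzyme that breaks down active vitamin D (chromosome 20, 54153449 to 54173973), rose from 6.61 ± 3.56 to 44.8 ± 10.7 CPM. THBS1, which encodes thrombospondin 1 (chromosome 15, 39581079 to 39599466), fell from 5463 ± 2840 to 254 ± 146 CPM (log2 fold change -4.43 ± 0.66). The chemokine genes CXCL3 and CXCL2, similar paralogs on chromosome 4 between which reads can be split, changed by -3.98 ± 0.49 and -2.73 ± 0.42. Other genes with large falls were FGL2 (-3.10 ± 0.41), RGL1 (-2.88 ± 0.52), OLFM1 (-2.77 ± 0.54), SLC46A2 (-2.58 ± 0.34) and GIMAP8 (-2.27 ± 0.41). PLA2G7 (-2.33 ± 0.50) and TDRD6 (-2.30 ± 0.58) also fell, and since their 3' ends overlap, some of their reads cannot be told apart.

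Among gene lists at 4 h, 15 of the 34 tested TGF-beta and SMAD target genes rose and 1, THBS1, fell (24 and 4 adjusted over the list alone). The list stood above other genes (camera adjusted p 2.64e-17), with adjusted p = 0.0957 with an estimated correlation. Of 18 targets of hypoxia-inducible factor, 6 rose (7 rose and 1 fell adjusted over the list alone), among them VEGFA, which encodes a vascular growth factor (2.21 ± 0.34), and the glucose transporter SLC2A1 (1.71 ± 0.44). That list had a camera adjusted p of 0.000804, and adjusted p = 0.0957 with an estimated correlation. Of 23 glycolysis genes, 4 rose (7 adjusted over the list alone), SLC2A1, SLC2A3 (1.16 ± 0.24), PGK1 (0.54 ± 0.13) and GAPDH (0.47 ± 0.13). The camera adjusted p was 9.59e-05, and adjusted p = 0.118 with an estimated correlation. Of 29 immediate-early and AP-1 genes, 4 rose (5 adjusted over the list alone), led by FOSB (1.71 ± 0.32) and KLF4 (1.30 ± 0.23), at a camera adjusted p of 0.00369 and adjusted p = 0.638 with an estimated correlation. Of 20 unfolded protein response genes, 4 rose (4 adjusted over the list alone), SLC7A5, DDIT4, SESN2 and ATF4, at a camera adjusted p of 0.000861 and adjusted p = 0.32 with an estimated correlation. SLC7A5 is an amino acid transporter, and DDIT4 and SESN2 restrain the growth kinase mTORC1. Of 13 Langerhans cell genes, 4 rose (5 adjusted over the list alone), including ID2 and the transcription factor RUNX3 (0.65 ± 0.15), at a camera adjusted p of 0.00369 and adjusted p = 0.175 with an estimated correlation. The 41 ribosomal protein genes had a median log2 fold change of 0.17 and a camera adjusted p of 0.00079, with adjusted p = 0.858 with an estimated correlation. Without donor 2 the direction of this list reversed (camera adjusted p 0.164), but this compares 1 untreated library with 1 treated library of another donor, so that treatment and donor are not separated. The 8 erythroid markers had a median log2 fold change of -4.02, with 0 of 8 past the test (camera adjusted p 0.231). Among them HBB, a haemoglobin gene, had a value of -5.33 ± 3.72, and of 0.12 ± 0.19 with donor as a block. In all, 448 genes rose and 189 fell at 4 h among 18719 tested, and 1026 rose and 509 fell with donor as a block. The count of 637 was 12 without donor 1 and 355 without donor 3, which leave a single library in 1 of the groups, and 185 without donor 2, which leaves a single library in both, of different donors. A single library was assumed to vary like those of the other groups. Within the libraries of this time alone it was 78, and with DESeq2 1078.

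At 8 h, 1432 genes were higher and 1302 lower (2265 and 2192 with donor as a block). The groups held 3 libraries each here and 2 at 4 h. In the simulated data, 23.9% of genes changed 1.5-fold were recovered at 8 h and 11.9% at 4 h, without the donor term. The recovery was closer for larger changes, at 43.3 and 37.3% for 2-fold and 69.7 and 57.6% for 4-fold. How much of the gap in counts this explains was not tested. The higher count than at 4 h therefore does not by itself show a wider effect. CYP24A1 stood at 136 ± 13.3 CPM with TGF-beta and 0.49 ± 0.23 CPM without, a log2 fold change of 8.10 ± 0.50 (edgeR adjusted p 3.05e-08). PALD1 rose from 9.96 ± 5.77 to 229 ± 10.2 CPM, and MMP2 from 12.6 ± 8.52 to 226 ± 33.8 CPM (4.16 ± 0.65). SERPINF1, which encodes pigment epithelium-derived factor, rose by 3.83 ± 0.22, the adhesion molecule NECTIN4 by 4.28 ± 0.29 and ANTXR1, a collagen-binding receptor, by 3.91 ± 0.34. LPAR5, LINC03040 and PLAU rose by 4.95 ± 0.47, 3.98 ± 0.56 and 3.80 ± 0.55, the last with 28.7% of its exon length overlapped by a gene on the other strand. THBS1 fell from 8411 ± 2410 to 119 ± 57.2 CPM (-6.15 ± 0.58). CD163, the scavenger receptor for haemoglobin-haptoglobin (chromosome 12, 7470813 to 7503893), fell from 429 ± 126 to 33.5 ± 14.1 CPM (-3.68 ± 0.45). SERPINB2 changed by -4.89 ± 0.78, the metalloreductase gene STEAP4 by -5.18 ± 0.83, NFXL1 by -4.30 ± 0.64 and ATP1B1, a sodium pump subunit, by -4.03 ± 0.50. The vanin genes VNN2 and VNN1, which are paralogs, changed by -3.96 ± 0.81 and -3.71 ± 0.65. CXCL3 (-4.03 ± 0.38) and RGL1 (-3.87 ± 0.43) fell here as at 4 h. All of these moved the same way in each of the 3 donors, which the rule for naming required.

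Of 44 interferon-stimulated genes, 10 fell at 8 h (18 adjusted over the list alone, 27 with donor as a block), among them MX2 (-1.70 ± 0.32), ISG15 (-1.42 ± 0.35) and HERC5 (-1.42 ± 0.38). The camera adjusted p was 5.32e-07, and adjusted p = 0.776 with an estimated correlation. Of 23 genes of alternative activation and scavenging, 7 fell and 2 rose (7 and 2 adjusted over the list alone). CD163 and the fatty acid receptor CD36 (-2.94 ± 0.22) fell, and the transglutaminase TGM2 rose (2.65 ± 0.52). That list had a camera adjusted p of 0.012, and adjusted p = 0.0936 with an estimated correlation. Of 35 inflammatory cytokines and chemokines, 9 fell and 4 rose (11 and 4 adjusted over the list alone), CXCL3 and CXCL2 among the former and TNFSF14, which encodes LIGHT, among the latter (2.58 ± 0.24). The camera adjusted p was 0.0114, and adjusted p = 0.776 with an estimated correlation. Of 21 sterol synthesis genes, 5 fell (6 adjusted over the list alone), including LSS (-1.03 ± 0.21), which encodes an enzyme of that pathway. Their camera adjusted p was 0.00163, and adjusted p = 0.776 with an estimated correlation. TGF-beta target genes were higher, with 24 of 34 up and 4 down (25 and 4 adjusted over the list alone), at a camera adjusted p of 6.52e-18 and adjusted p = 0.0936 with an estimated correlation. Langerhans cell genes had 7 of 13 up and 1 down (7 and 1 adjusted over the list alone), at a camera adjusted p of 0.00167 and adjusted p = 0.147 with an estimated correlation. Glycolysis genes had 7 of 23 up and 1 down (8 and 1 adjusted over the list alone), with LDHA, lactate dehydrogenase A, up by 1.79 ± 0.20, at a camera adjusted p of 0.012 and adjusted p = 0.45 with an estimated correlation. The ribosomal protein genes had a median log2 fold change of 0.14, at a camera adjusted p of 0.0123 and adjusted p = 0.985 with an estimated correlation. The count of 2734 genes was 945 without donor 1 and 1758 without donor 2.

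The count of changed genes was highest at 12 h, with 1939 genes higher and 2122 lower (2880 and 3215 with donor as a block). CYP24A1 stood at 134 ± 41.8 CPM with TGF-beta against 7 reads in all 3 untreated libraries together, a ratio of 1460 with a 95% interval of 711 to 3640 that covers counting error only. LINC03040 rose by 5.95 ± 0.65, PALD1 by 5.36 ± 0.42, MMP2 by 5.09 ± 0.68 and FGD5 by 5.13 ± 0.50. PROC, which encodes the anticoagulant protein C, rose from 3.77 ± 1.97 to 109 ± 19.0 CPM (4.84 ± 0.40). MCEMP1, a mast cell and myeloid membrane protein (chromosome 19, 7676628 to 7679826), rose from 14.0 ± 7.39 to 375 ± 72.9 CPM (4.75 ± 0.50), and SHISAL2A rose by 4.72 ± 0.63. THBS1 fell by 6.61 on the log2 scale. ATP1B1 (-4.84 ± 0.50), NFXL1 (-4.65 ± 0.64), STEAP4 (-4.40 ± 0.81), VNN2 (-4.22 ± 0.83), SERPINB2 (-4.10 ± 0.79) and LINC00877 (-4.01 ± 0.44) also fell. GAS7 fell from 514 ± 64.9 to 29.1 ± 6.64 CPM (edgeR adjusted p 5.17e-09). CD163 fell from 1432 ± 501 to 96.8 ± 34.2 CPM and the lectin CLEC10A from 208 ± 40.4 to 18.2 ± 9.59 CPM. All of these moved the same way in each of the 3 donors, which the rule for naming required.

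At 12 h, 24 of 44 interferon-stimulated genes fell and 2 rose (31 and 2 adjusted over the list alone), with IFIT1 at -2.84 ± 0.65, SIGLEC1 at -2.80 ± 0.65, RSAD2 at -2.45 ± 0.63 and IFIT2 at -2.23 ± 0.52. The camera adjusted p was 1.25e-08, and adjusted p = 0.669 with an estimated correlation. Of 23 scavenger and alternative activation genes, 11 fell and 2 rose (11 and 3 adjusted over the list alone), at a camera adjusted p of 0.00552 and adjusted p = 0.0793 with an estimated correlation. Of the TGF-beta target genes, 25 rose and 2 fell (28 and 2 adjusted over the list alone), and LTBP2, which encodes a latent TGF-beta binding protein, rose by 4.08 ± 0.47. That list had a camera adjusted p of 4.94e-18, and adjusted p = 0.0793 with an estimated correlation. The Langerhans cell genes had 7 of 13 up and 1 down (7 and 1 adjusted over the list alone), with the receptor kinase AXL up by 3.19 ± 0.45, at a camera adjusted p of 0.000884 and adjusted p = 0.126 with an estimated correlation. Immediate-early genes had 11 of 29 up and 3 down (11 and 3 adjusted over the list alone), with FOSB up by 2.06 ± 0.28 and the macrophage transcription factor MAF at -2.00 ± 0.61. Their camera adjusted p was 0.00281, and adjusted p = 0.565 with an estimated correlation. Glycolysis genes had 9 of 23 up and 2 down (11 and 2 adjusted over the list alone), at a camera adjusted p of 0.00382 and adjusted p = 0.305 with an estimated correlation. Genes of the extracellular matrix and its proteases had 10 of 37 up and 6 down (15 and 7 adjusted over the list alone), at a camera adjusted p of 0.0367 and adjusted p = 0.305 with an estimated correlation. A list of neutrophil markers had 4 of 10 up (5 adjusted over the list alone), including CSF3R, the G-CSF receptor that monocytes also express (1.19 ± 0.14), at a camera adjusted p of 0.018 and adjusted p = 0.437 with an estimated correlation. Sterol synthesis genes had 7 of 21 lower (11 lower and 1 higher adjusted over the list alone), at a camera adjusted p of 0.000884 and adjusted p = 0.669 with an estimated correlation. Respiratory chain genes had 4 of 37 lower (4 adjusted over the list alone), at a camera adjusted p of 0.0226 and adjusted p = 0.981 with an estimated correlation. The count of 4061 genes was 1698 without donor 1.

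At 36 h fewer genes passed the test, 859 higher and 660 lower (1693 and 1556 with donor as a block). MCEMP1 stood at 148 ± 12.5 CPM with TGF-beta and 3.02 ± 1.59 without (5.60 ± 0.53), and HTRA1, a secreted serine protease, at 227 ± 29.1 and 9.98 ± 9.68 CPM (4.49 ± 0.52). The signalling protein WNT5A rose by 4.81 ± 0.57, FGD5 by 4.77 ± 0.49, PLEK2 by 4.25 ± 0.29 and PROC by 4.12 ± 0.42. CYP24A1 was still higher, at 17.7 ± 5.50 CPM against 7 reads in all 3 untreated libraries together, 2 of which had none, a ratio of 172 with a 95% interval of 83.1 to 428 for counting error. The untreated level also rested on few reads for LINC03040 (5 reads) and the cytokine LIF (8 reads), which stood at 2.12 ± 1.46 and 2.76 ± 0.59 CPM with TGF-beta. F13A1, which encodes the A subunit of clotting factor XIII (chromosome 6, 6144085 to 6321013), stood at 8.16 ± 7.31 CPM with TGF-beta and 313 ± 283 without (-5.26 ± 0.77). CFP, which encodes the complement regulator properdin, fell from 134 ± 28.4 to 8.12 ± 0.937 CPM (edgeR adjusted p 4.88e-10). SIGLEC1, an adhesion receptor of macrophages that interferon induces, changed by -3.88 ± 0.67, OLFM1 by -3.59 ± 0.40, LINC00877 by -3.45 ± 0.46 and THBS1 by -4.00 ± 0.53. SERPINB2 (-5.40 ± 0.93), STEAP4 (-5.37 ± 0.89), NRG1 (-4.93 ± 1.34) and MMP9 (-4.17 ± 0.87) fell as well, the last with 18.4% of its exon length overlapped by an antisense gene. All of these moved the same way in each of the 3 donors, which the rule for naming required.

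Scavenger and alternative activation genes were lower at 36 h, with 8 of 23 down and 2 up (9 and 2 adjusted over the list alone). Their camera adjusted p was 6.7e-06, and adjusted p = 0.00333 with an estimated correlation. Targets of the liver X receptor, a sensor of sterols, had 7 of 15 up (10 adjusted over the list alone). APOE rose from 127 ± 88.3 to 1750 ± 824 CPM (3.78 ± 0.70), the cholesterol exporter ABCG1 by 2.80 ± 0.41 and PLTP by 1.41 ± 0.34, at a camera adjusted p of 3.99e-07 and adjusted p = 0.206 with an estimated correlation. TGF-beta target genes had 20 of 34 up and 1 down (23 and 2 adjusted over the list alone), at a camera adjusted p of 6.91e-16 and adjusted p = 0.0718 with an estimated correlation. Langerhans cell genes had 6 of 13 up and 1 down (6 and 1 adjusted over the list alone), with the integrin gene ITGAE up by 2.14 ± 0.42, at a camera adjusted p of 0.00285 and adjusted p = 0.206 with an estimated correlation. Interferon-stimulated genes had 6 of 44 lower (14 adjusted over the list alone, 20 with donor as a block), with IFITM3 at -1.45 ± 0.26, at a camera adjusted p of 1.78e-05 and adjusted p = 0.73 with an estimated correlation. Dendritic cell genes had 5 of 22 down and 1 up (8 and 1 adjusted over the list alone), among them CLEC10A (-3.05 ± 0.41) and CD209 (-2.20 ± 0.38), at a camera adjusted p of 0.00499 and adjusted p = 0.206 with an estimated correlation. Ribosomal protein genes had 5 of 41 lower (11 adjusted over the list alone, 24 with donor as a block) and a median of -0.29, at a camera adjusted p of 5.44e-11 and adjusted p = 0.62 with an estimated correlation. Glycolysis genes had 5 of 23 up (5 up and 1 down adjusted over the list alone), at a camera adjusted p of 0.00701 and adjusted p = 0.346 with an estimated correlation. The neutrophil list had 4 of 10 up and 1 down (4 and 1 adjusted over the list alone), with FCGR3B, whose reads can be split with its paralog FCGR3A, at 2.35 ± 0.29. Its camera adjusted p was 0.0475, and adjusted p = 0.562 with an estimated correlation. Libraries of this time also differed in other measures. Mitochondrial transcripts took 4.53 to 6.55% of the reads with TGF-beta and 6.38 to 7.72% without, against 2.91 to 4.2% over all libraries of the earlier times. Mitochondrial rRNA, which is part of this share, took 1.5 to 3.13% with TGF-beta and 3.06 to 3.47% without. With donor as a block, 5 of 14 NK cell markers were lower and 1 higher with TGF-beta (camera adjusted p 0.000734), 5 of 13 B cell markers were lower (camera adjusted p 0.00115), with adjusted p = 0.48 for both with an estimated correlation and the block. Without the block the camera adjusted p was 0.246 and 0.238. The count of 1519 genes was 397, 989 and 895 without donors 1, 2 and 3, and 867 within the libraries of this time alone.

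**Figure D2:**
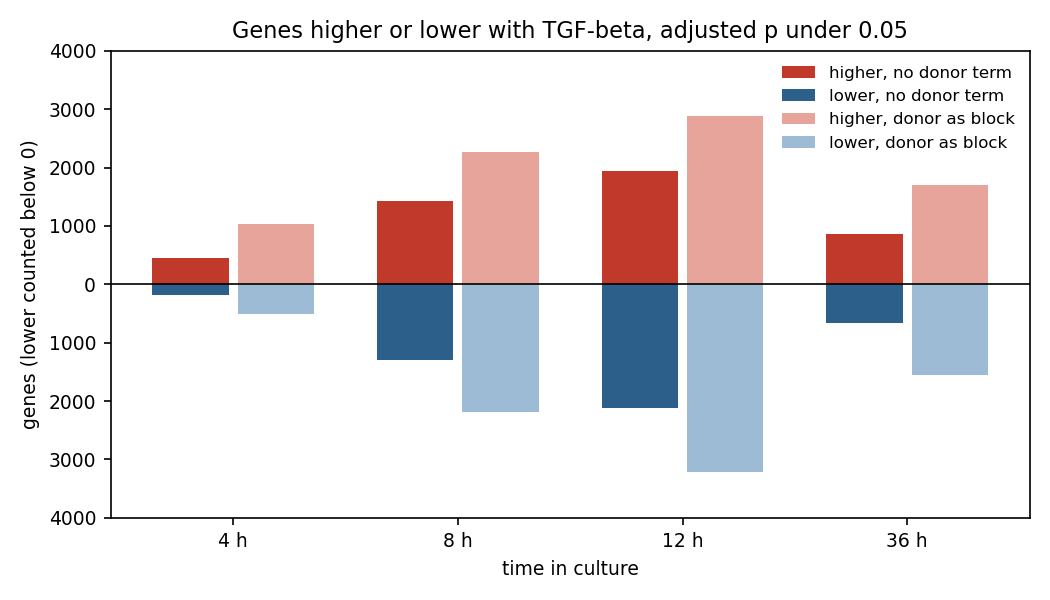
Number of genes higher (above the zero line) and lower (below it) with TGF-beta at each time at an adjusted p under 0.05, in the fit without a donor term (dark) and with donor as a block (light). In both fits the count was highest at 12 h, with 1939 higher and 2122 lower without the donor term.

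Averaged over the 4 times, 2756 genes were higher and 2778 lower with TGF-beta. The libraries of one donor and treatment are not independent donors, so this test measures agreement over times as well as donors. CYP24A1 had the largest mean rise (7.17 ± 0.29), followed by LINC03040 (4.36 ± 0.35), MMP2 (4.06 ± 0.36), FGD5 (3.81 ± 0.25), MCEMP1 (3.77 ± 0.26), PMEPA1 (3.67 ± 0.29), PALD1 (3.66 ± 0.21), NECTIN4 (3.53 ± 0.15) and LPAR5 (3.45 ± 0.24). THBS1 had the largest mean fall (-5.30 ± 0.31), followed by STEAP4 (-4.41 ± 0.45), SERPINB2 (-4.40 ± 0.44), NFXL1 (-3.52 ± 0.34), ATP1B1 (-3.22 ± 0.26), RGL1 (-2.87 ± 0.22), VNN2 (-2.83 ± 0.42), OLFM1 (-2.83 ± 0.22), VNN1 (-2.80 ± 0.34) and NRG1 (-2.80 ± 0.62). Mean values of the check genes were 2.16 ± 0.10 for SMAD7, 1.17 ± 0.09 for TGFBI, 0.81 ± 0.10 for SKIL and 1.27 ± 0.08 for TGFB1. Of the TGF-beta target genes, 28 of 34 were higher and 4 lower (28 and 4 adjusted over the list alone), at a camera adjusted p of 5.05e-19. The adjusted p was 0.0399 with an estimated correlation, and 0.104 with the donor block as well. Of the scavenger and alternative activation genes, 13 of 23 were lower and 3 higher (14 and 3 adjusted over the list alone), at a camera adjusted p of 0.00102, with adjusted p = 0.0368 with an estimated correlation. Of the interferon-stimulated genes, 28 of 44 were lower and 1 higher (32 and 2 adjusted over the list alone), at a camera adjusted p of 5.5e-08, with adjusted p = 0.691 with an estimated correlation. The count of 5534 genes was 2931 without donor 1, and 2305 when the counts of 8, 12 and 36 h were summed per donor and treatment (6729 with donor as a block).

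**Figure D3:**
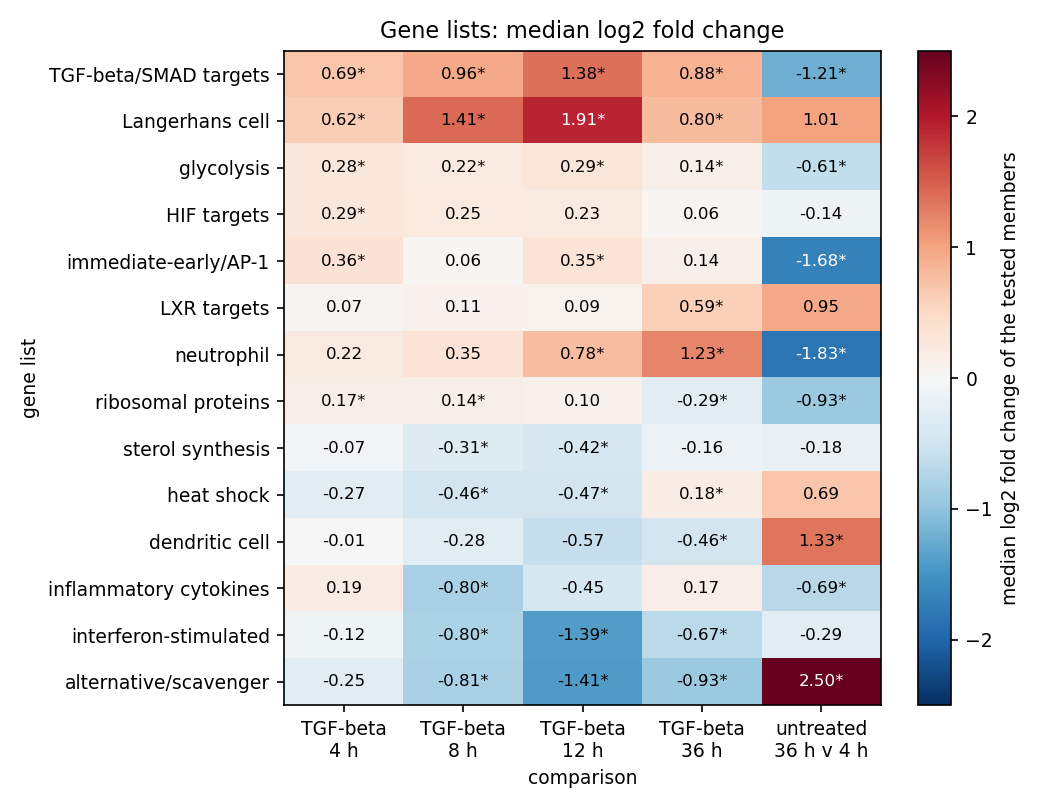
Median log2 fold change of the tested members of 14 gene lists (vertical axis) in the 4 TGF-beta comparisons and in untreated cells at 36 h against 4 h (horizontal axis), with red for higher, blue for lower and an asterisk for a camera adjusted p under 0.05 with the preset correlation. The interferon-stimulated median was -0.80 at 8 h, -1.39 at 12 h and -0.67 at 36 h.

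Untreated cells at 36 h were compared with untreated cells at 4 h to describe the change in culture on which TGF-beta acted. TREM2, a lipid-sensing receptor, went from 0.633 ± 0.139 to 123 ± 82.4 CPM (7.58 ± 0.82), MRC1, the mannose receptor, from 1.48 ± 0.35 to 203 ± 88.9 CPM, and the transporter SLCO2B1 from 1.65 ± 0.819 to 267 ± 30.6 CPM. The apolipoprotein gene APOE (chromosome 19, 44905754 to 44909393) rose by 7.01 ± 1.06. Its neighbour APOC1 rose by 7.77 ± 0.97 from 9 reads in the untreated 4 h libraries, and 45.9% of its exon length is shared with a readthrough gene, so its value is uncertain. TREM1, which amplifies inflammatory signals, fell from 333 ± 2.98 to 3.00 ± 1.57 CPM (-6.78 ± 0.40). SYN1 (-7.55 ± 0.35), CYP1A1, a target of the aryl hydrocarbon receptor (-7.36 ± 1.08, with 19 reads in the untreated 36 h libraries), NTSR1 (-6.94 ± 0.30) and S1PR3 (-6.75 ± 0.66) fell too. These 10 genes moved the same way in both donors with libraries at both times, which the rule for naming required. Of 33 macrophage maturation genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p 0.000243), with adjusted p = 0.317 with an estimated correlation. Of 24 classical monocyte genes 14 fell (14 fell and 1 rose adjusted over the list alone; camera adjusted p 0.000243), among them FPR2 (-5.06 ± 0.30) and S100A12 (-4.06 ± 0.45), with adjusted p = 0.19 with an estimated correlation. FPR2 and S100A12 are expressed by neutrophils as well, and of 10 neutrophil markers 7 fell (8 adjusted over the list alone; camera adjusted p 0.00581), among them CMTM2 (-4.85 ± 0.85, with 4 reads in the untreated 36 h libraries), KCNJ15 (-4.37 ± 0.69) and MGAM (-3.47 ± 0.37), with adjusted p = 0.274 with an estimated correlation. Immediate-early genes had 21 of 29 down and 2 up (21 and 2 adjusted over the list alone; camera adjusted p 6.6e-08), with adjusted p = 0.243 with an estimated correlation. Ribosomal protein genes had 40 of 41 down (40 adjusted over the list alone; camera adjusted p 1.88e-13), with adjusted p = 0.317 with an estimated correlation. TGF-beta target genes had 22 of 34 down and 3 up (23 and 3 adjusted over the list alone; camera adjusted p 7.66e-07), with adjusted p = 0.274 with an estimated correlation. MHC class II genes had 12 of 15 up and 1 down (12 and 1 adjusted over the list alone; camera adjusted p 0.000636), among them CIITA, their transcriptional activator (2.55 ± 0.28), with adjusted p = 0.298 with an estimated correlation. Scavenger and alternative activation genes had 15 of 23 up and 2 down (15 and 2 adjusted over the list alone; camera adjusted p 0.0142), with adjusted p = 0.19 with an estimated correlation. Markers of T, B and NK cells had median log2 fold changes of 1.28, 2.31 and 1.65. Of these, 1 of 18, 4 of 13 and 5 of 14 passed the test without a donor term, and 17, 13 and 11 with donor as a block. Mitochondrial transcripts took a mean of 3.34% of the reads at 4 h and 6.89% at 36 h, of which mitochondrial rRNA took 0.73 and 3.27%. In total 5382 genes rose and 4698 fell, a count of 10080 that was 6553 without donor 1, which leaves a single untreated library at 4 h.

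The TGF-beta effects at 36 h and at 4 h were compared directly by an interaction test, which 88 genes passed with a higher and 104 with a lower effect at 36 h (469 and 572 with donor as a block). Without that block, donor differences enter the 4 h effects, since only donor 2 was in both groups at 4 h. F13A1 had an effect of 0.11 at 4 h and -5.26 at 36 h, a difference of -5.37 ± 1.09 (edgeR adjusted p 0.0215). For CFP the difference was -3.54 ± 0.27 (adjusted p 2.98e-06). GGTA1, a pseudogene in humans, PTGIR, the prostacyclin receptor, and LINC00877 had differences of -3.52 ± 0.66, -3.07 ± 0.46 and -2.87 ± 0.65. In the other direction, CYP24A1, WNT5A and MCEMP1 had differences of 4.58 ± 0.83, 4.28 ± 0.79 and 3.76 ± 0.72. With TGF-beta, CYP24A1 stood at 44.8 ± 10.7 CPM at 4 h and 17.7 ± 5.50 CPM at 36 h. Without it, the level was 6.61 ± 3.56 CPM at 4 h and rested on 7 reads at 36 h. For CXCL3 (3.62 ± 0.58) and SLC46A2 (3.58 ± 0.43) an effect below 0 at 4 h was followed by values of -0.36 and 1.00 at 36 h. Of 41 ribosomal protein genes 1, RPS13, had a lower effect at 36 h (19 adjusted over the list alone, 21 with donor as a block), at a camera adjusted p of 2.18e-18 and adjusted p = 0.804 with an estimated correlation. Of 15 liver X receptor targets 1, SMPDL3A, had a higher effect at 36 h (3 adjusted over the list alone), at a camera adjusted p of 0.00119 and adjusted p = 0.804 with an estimated correlation. Of 12 heat shock genes 1, HSPH1, had a higher effect at 36 h (4 adjusted over the list alone), at a camera adjusted p of 0.00119 and adjusted p = 0.804 with an estimated correlation. With fry, 0 lists were called in this comparison. The erythroid markers had a median difference of 3.43, with 0 of 8 past the test (camera adjusted p 0.335). An effect that differed among any of the 4 times was found for 730 genes (2856 with donor as a block). Each donor left out leaves a single library in 1 of the 4 h groups, or in both without donor 2, assumed to vary like the other groups. The 192 genes of the direct comparison became 2, 21 and 77 without donors 1, 2 and 3, and the 730 became 20, 142 and 221. With DESeq2 the counts were 524 and 1657, and a stricter filter on low counts gave 290 in the direct comparison. Without the 36 h libraries, 96 genes differed among the remaining times.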

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

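The tests of the first 2 patterns below were chosen after the pattern was seen, except the depth test, and in the third only the comparison of the median with matched random lists was chosen before. The following results were flagged because the TGF-beta effect on a gene differed between 36 h and 4 h in the interaction test, and each is given as the difference in log2 fold change with the effects at 4 and 36 h. Effects lower at 36 h were those on F13A1 (-5.37, from 0.11 to -5.26), CFP (-3.54, from -0.50 to -4.04), GGTA1 (-3.52, from 0.39 to -3.13), PTGIR (-3.07, from -0.11 to -3.18), LINC00877 (-2.87, from -0.58 to -3.45), GADD45G (-2.35, from 2.81 to 0.46) and SOX4 (-2.04, from 2.82 to 0.78). Effects higher at 36 h were those on PLEK2 (2.54, from 1.71 to 4.25), PROC (2.76, from 1.36 to 4.12), CXCL2 (2.78, from -2.73 to 0.05), ANTXR1 (3.18, from 0.72 to 3.90, with 19 reads in the untreated 4 h libraries), HTRA1 (3.54, from 0.95 to 4.49), SLC46A2 (3.58, from -2.58 to 1.00), CXCL3 (3.62, from -3.98 to -0.36), MCEMP1 (3.76, from 1.84 to 5.60), WNT5A (4.28, from 0.53 to 4.81) and CYP24A1 (4.58, from 2.77 to 7.35). For CYP24A1 the untreated 36 h level rested on 7 reads, and the level with TGF-beta was 44.8 CPM at 4 h and 17.7 CPM at 36 h. The larger difference at 36 h is therefore not a higher treated level. The differences above are without the donor block, and at 4 h only donor 2 was in both groups. Groups of 2 or 3 libraries were not tested for outliers.

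TGF-beta effects at 12 h opposed the change of untreated cells from 4 to 36 h in 2447 of the 2918 genes past both tests (83.9%), against 1097 opposed and 1090 the same way if the calls were independent. The share was 75% at 8 h, where as at 12 h no library is shared with the culture comparison, and 76.6 and 75.5% at 4 and 36 h, where the untreated libraries are shared, and the correlation over all tested genes was -0.05, -0.21, -0.34 and -0.32 at 4, 8, 12 and 36 h. Scaling of the libraries would make only one direction opposed, and the lower of the opposed shares among genes that rose and genes that fell was 82%, which argues against it. Fewer lymphocytes in the treated 12 h libraries would make the marker difference at 12 h negative, but its lowest donor median was 0.09. The other times were not tested in this way. At 36 h the T, B and NK cell markers had median log2 fold changes of -0.06, -0.47 and -0.65 with TGF-beta. Fewer lymphocytes therefore stay open for the share at 36 h. Slowing of the culture change is not the whole effect of TGF-beta, since 16.1% of genes moved the same way, among them APOE (4.57 at 12 h, 7.01 in culture) and PLAU (3.41 and 4.79) upward and THBS1 (-6.61 and -2.65) downward.

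TGF-beta changed 1519 genes at 36 h against 4061 at 12 h. Lower depth did not account for it: with all libraries thinned to 16.85 M reads the counts were 1422 and 3624, a ratio of 2.55. Larger constant differences between donors did not account for all of it, since the ratio was 1.88 with the donor block within each time. That block does not remove differences between donors in the response to TGF-beta, so larger ones at 36 h stay open. Genes that responded early had a smaller effect at 36 h: over the 2734 genes past the test at 8 h, the median effect in their direction was 0.82 at 12 h and 0.28 at 36 h, and the highest ratio in a donor was 0.378. Of these genes, 98.6% kept their direction at 12 h and 79.3% at 36 h.

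Markers of T, B and NK cells were higher in untreated 36 h than 4 h libraries although the cells were selected for CD14, which lymphocytes lack. In both donors with libraries at both times at least 94.4% of the markers of each list were higher, and IL7R, for example, stood at 57.0 ± 35.6 and 152 ± 104 CPM and MS4A1 at 8.28 ± 4.38 and 45.1 ± 29.4 CPM. A smaller share of monocyte RNA would raise all other cell types alike. With donor as a block, the upper quartiles were 0.89 for platelet and 0.79 for erythroid markers, against a lower quartile of 1.42 for lymphocyte markers. Platelet markers did not move alike (3.68 for TREML1, -3.08 for CAVIN2), so they need not follow platelet RNA. Markers of plasmacytoid dendritic cells had a median of 1.45 (quartiles 0.5 and 2.07), between the lymphocyte quartiles of 1.42 and 2.53. Neutrophil markers had a median of -1.81, though monocytes express some of them, such as CSF3R. The 5 stromal and endothelial markers had a median of -1.6. These lists differ, and a smaller share of monocyte RNA stays open. Against an effect of normalization on weak genes, the lymphocyte median of 2.09 with that block (1.64, 2.55 and 2.05 for T, B and NK cells) was at percentile 100 of 10000 matched random lists, whose highest median was 1.31. More lymphocyte RNA stays open: it would shift the markers of a type alike, and their interquartile range was at percentiles 3.83, 0.06 and 6.67 of matched random lists for T, B and NK cells, not under the bound of 5 in all 3.

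Exchanging treatment labels between libraries gave at most 0 genes in the other splits at 8 and 12 h and 7 at 36 h, against 2734, 4061 and 1519, but 10 splits are too few for a share under 0.05 (1 split reached the real count at each time, the real one). For the average, the highest other of 60 splits gave 240 genes against 5534 (1 of 60 reached it, the real one). These exchanges ignored donors, although libraries of a donor are alike. Only 3 of the 60 splits, the real one included, put the 2 libraries of each donor and time on different sides. The highest other of those gave 58 genes, and they are too few for a share under 0.05.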

How the results depend on the processing

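The choices of times and the donor block with an estimated correlation were added after the results were seen, and all other settings were chosen before. No named gene that passed a test reversed under any setting in the comparison where it passed. Values that did not pass could change sign, as for HBB at 4 h (-5.33, and 0.12 with the donor block). Without donor 1, 627 of 909 gene results kept their side of the threshold and 281 became weaker, and with counts summed per donor 104 of 152 kept theirs and 48 became weaker. These settings have fewer libraries. Of 909 gene results, 896 kept their side of the threshold with RLE scaling, 888 with the donor block, 824 without a filter, 726 without donor 2 and 776 without donor 3, and 880 of 890 with DESeq2. The donor block changed no list call that the preset correlation gave (71 of 71 the same). Gene counts that moved by over 1.5 times were as follows; unless stated, the cause was not tested. With the donor block they were 1535 at 4 h, 4457 at 8 h, 6095 at 12 h, 3249 at 36 h, 1041 for the effect at 36 h against 4 h and 2856 for any difference among times. Each donor left out leaves a single library in a 4 h group, assumed to vary like the other groups, and donor 2 in both, then of different donors. Without each donor in turn they ran from 12 to 355 at 4 h, 945 to 2003 at 8 h, 1698 to 2947 at 12 h, 397 to 989 at 36 h, 2931 to 4486 for the average, 6553 to 9833 for untreated 36 h against 4 h, 2 to 77 for the effect at 36 h against 4 h, and 20 to 221 for any difference. DESeq2 gave 1078 at 4 h, 524 for the effect at 36 h against 4 h and 1657 for any difference, and the strict filter 290 for the effect at 36 h against 4 h. Only the libraries of the groups compared gave 78 at 4 h and 867 at 36 h, and with the donor block 5485 at 8 h, 6610 at 12 h and 3519 at 36 h. Counts of 8, 12 and 36 h summed per donor gave 2305 for the average, and 6729 with the donor block. Without the 36 h libraries any difference among times held 96 genes. With 12 h in place of 36 h the counts were 6367 for the change in culture and 307 for the difference of effects, and with 8 h in place of 4 h the latter was 602. The donor block within the 4 h libraries alone was not run, since it leaves no residual degrees of freedom. Gene lists called numbered 7, 10, 11 and 10 at 4, 8, 12 and 36 h, 10 in the average, 17 in culture and 6 for the difference of effects. With an estimated correlation they numbered 0, 0, 0, 1, 2, 0 and 0, and with the donor block as well 0, 0, 0, 1, 1, 0 and 0. With fry they were 19 in the average, 31 in culture and 0 for the difference of effects, which with the donor block had 15 and without each donor 7 to 12. The ribosomal protein list at 4 h reversed without donor 2 (camera adjusted p 0.164), where treatment and donor are not separated and which gave the highest adjusted p of the settings without a donor, and the lowest was 2.22e-11 without donor 3. Depth limits the genes with few reads: 7 reads set the untreated level of CYP24A1 at 12 and at 36 h.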

Other observations

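The gene lists below were fixed before the data were examined, but which lists and genes to describe here was chosen after their values were seen. Several genes of the TGF-beta pathway itself changed. TGFBR1, a receptor of the ligand, rose by log2 fold changes of 1.90 ± 0.19, 2.11 ± 0.19 and 1.47 ± 0.19 at 8, 12 and 36 h, and the integrin gene ITGAV, whose product activates latent TGF-beta, by 1.90 ± 0.18, 2.34 ± 0.18 and 1.75 ± 0.18. NRROS, which holds latent TGF-beta on myeloid cells, fell by 2.74 and 2.81 on this scale at 8 and 12 h, and LRRC32 (-1.92 ± 0.42, with 17 reads in the treated libraries) and SMAD3 (-1.62 ± 0.38) fell at 36 h. Of the 25 tested pathway components, 9 rose and 5 fell at 12 h (10 and 8 adjusted over the list alone), with a camera adjusted p of 0.323. Among genes that detect microbes or form inflammasomes, CASP1 fell at each time (-1.54 ± 0.17, -2.14 ± 0.14, -2.29 ± 0.14 and -1.34 ± 0.14) and NLRP3 at 8, 12 and 36 h (-1.15 ± 0.13, -1.20 ± 0.13 and -1.36 ± 0.13). NLRP12 rose by 1.74 ± 0.23, 2.78 ± 0.24 and 1.25 ± 0.24 at those times. Of 25 genes of this list 6 rose and 3 fell at 12 h (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.641.

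Among chemotactic receptors, the scavenging receptor gene ACKR3 rose by 3.66 ± 0.50, 4.67 ± 0.55 and 2.45 ± 0.49 at 8, 12 and 36 h, and CYSLTR1, a leukotriene receptor, fell at 12 h (-2.08 ± 0.31) and 36 h (-1.49 ± 0.30). Of 25 such genes 6 rose and 8 fell at 12 h (6 and 9 adjusted over the list alone; camera adjusted p 0.915). Of 28 genes linked to suppressive myeloid cells, 8 rose and 8 fell at 12 h (8 and 8 adjusted over the list alone; camera adjusted p 0.693). VEGFA (3.56 ± 0.30) and OLR1, a receptor for oxidized LDL (2.95 ± 0.49), rose, and the immune checkpoint ligand genes PDCD1LG2 (-2.49 ± 0.73) and CD274 (-2.19 ± 0.72) fell. The complement gene C3 rose by 2.81 ± 0.40, 3.83 ± 0.42 and 3.75 ± 0.42 at 8, 12 and 36 h, while C1QA fell at 36 h (-2.53 ± 0.69). Of 12 heat shock genes, 6 fell and 1 rose at 12 h (7 and 1 adjusted over the list alone). HSP90AB1 (-0.78 ± 0.10) and HSPD1 (-0.76 ± 0.10) fell and BAG3 (0.67 ± 0.18) rose, at a camera adjusted p of 0.00739 and adjusted p = 0.692 with an estimated correlation. The list was also lower at 8 h (median -0.46, camera adjusted p 0.012, and 0.776 with an estimated correlation). At 36 h it was called in the other direction (median 0.18, camera adjusted p 0.0219, and 0.73 with an estimated correlation), with 0 of 12 genes past the test.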
